A study of Homo sapiens with 139 samples.

How the data were processed

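Single trophoblast cells were taken from human embryos in extended culture on days 8, 10 and 12, and their RNA was amplified with a Smart-seq2 type kit, made into tagmented libraries and sequenced in paired-end reads, per the labels' protocols. The lineage of each cell (CTB, STB or MTB) is the submitters' annotation in the labels, and no clustering was done. Reads were processed with FastQC, STAR 2.5.3a, Partek and hg38, per the submitters' processing notes, which do not give the order or role of each tool. Neither the strand of the reads nor any batch is stated in the labels.

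The deposited file holds RPKM values with 0.01 added to each, computed by the authors over the genomic span of each gene with introns included. Neither the offset nor the span is stated, so both were read from the values. For 3539 genes with 1 transcript and several exons, a median over cells of 70.8% of the low values were whole numbers of reads within 0.05 read when the genomic span was used, against 6.22% with the exon length. Whole reads were not recovered for every value, so the values were not treated as counts. They were converted to CPM (reads scaled to 1e6 per cell) by subtracting 0.01 and multiplying by the span in kilobases. This was decided from the unit, before any result was computed, and the plan for counts did not apply.

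It held 26932 rows, of which 16434 were protein-coding and 4842 pseudogenes. Rows of Y-linked genes, XIST and TSIX (69) were removed unread, which left 26863. All 135 value columns were mapped to samples, 1 of them to the sample whose title lacks a lineage letter and whose description gives CTB. Of the 139 labelled samples 4 had no column and were not analysed here, 2 of day 8 STB, 1 of day 8 CTB and 1 of day 10 CTB. Of the values 47.5% were at the offset. A median of 13930 genes was detected per cell (6123 to 17755), and 1 cell lay under 6965, 0.5 of the median. The listed genes took a median of 63.3% of the reads of a cell (38.8 to 70.8%).

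The implied depth was found from the step between low values and had a median of 6.78 M reads per cell, from 0.0328 to 20.5 M. By group the median was 6.17 M in day 8 CTB, 6.96 in day 10 CTB, 7.28 in day 12 CTB, 6.35 in day 8 STB, 6.66 in day 10 STB, 6.28 in day 12 STB and 7.29 in MTB. At the median depth 1 read is under 0.2 CPM in a cell, and 5 cells had under 3 M reads. Of 9045 pairs of cells none had identical values, the highest correlation was 0.983 against a median of 0.739, and 3 pairs lay over 0.97, each within 1 embryo and lineage. Their differences exceeded counting noise, with a chi-square per gene of 19.6, 3.54 and 14.0 against 1 expected for a library sequenced again, among genes of at least 20 reads.

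Cells were averaged by embryo and lineage into 18 sums in 7 groups, each embryo being a replicate. The 4 MTB cells without an embryo number were kept out of the tests. Log2 of the mean plus 1 was computed from the deposited values so converted, genes with a mean of at least 1 in at least 3 sums were kept (13990), and 1 model with a mean per group was fitted with limma 3.58.1 and an intensity trend. It left 11 residual and 7.61 prior degrees of freedom. The MTB and day 8 STB groups hold 1 embryo each, which was assumed to vary like the others. P values were adjusted by the Benjamini-Hochberg method and called at 0.05. STB was compared with CTB averaged over days 10 and 12 (5 STB and 7 CTB sums), on each of these days, and between them. MTB was compared with CTB and STB of day 12, CTB between days 8, 10 and 12, and STB between days 10 and 12. The day 8 STB cells and unnumbered MTB cells entered counts of directions alone. The latter share their CTB controls with the numbered cells, so 100 sets of unchanged groups were simulated against those controls.

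CTB and STB of 1 embryo are paired by design. Their deviations from the group means correlated at 0.138, 0.0905 and 0.151 in day 10 embryos 1, 2 and 4, and at 0.192 and -0.0503 in day 12 embryos 4 and 6, with a consensus of 0.197. The planned fit had no block, and that with embryos as a block was an alternative. In the MTB comparisons that block rests on MTB of embryo 4 with CTB and STB of embryos 4 and 6.

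Before the data were examined, 27 gene lists with 640 genes were fixed. They cover pan-trophoblast, cytotrophoblast, syncytin and fusion, placental hormones, pregnancy-specific glycoproteins, steroid synthesis, cholesterol synthesis, extravillous trophoblast, epithelial-mesenchymal transition, matrix proteases and basement membrane, interferon-stimulated genes, interferon ligands and receptors, S phase, G2 and M phase, CDK inhibitors and senescence, hypoxia and glycolysis, oxidative phosphorylation, mitochondrially encoded genes, endoplasmic reticulum stress and secretion, early response and heat shock, solute transporters, imprinted genes, and WNT, BMP and FGF signalling. The remaining lists, epiblast, hypoblast, amnion and extra-embryonic mesenchyme, and immune, endothelial and blood, are markers of other cell types. Lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated. A list's direction in camera is relative to all other genes. Members were also adjusted over their list alone.

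Genes named in the text follow a rule fixed beforehand. Among genes past the threshold whose sums do not overlap between the groups (for the average, on both days) and whose mean in the higher group is at least 10, these are the 6 with the largest rise and the 6 with the largest fall, leaving out clone-type names, with up to 3 members of each list with the largest change. Where fewer than 12 genes passed, all were eligible. The markers GATA3, KRT7, TP63, CDH1, CGA, SDC1, ERVW-1, HLA-G, MMP2, ISG15, IFI27, MKI67, POU5F1 and GATA6 were reported in any case. Among eligible genes, those that passed without each embryo in turn were preferred in the text. Near-identical genes of the CGB, PSG and CSH families, and pseudogenes such as MTCO2P12, can share reads, as can antisense partners, so their values are uncertain. Coordinates are those of the table on hg38, 1-based.

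The alternatives were quantile normalization, no intensity trend, no filter, a pseudocount of 0.1, only the groups compared, the embryo as a block, the mean over cells of log2 values, cells or sums left out, other uses of the unnumbered MTB cells, and a minimum log2 fold change of 1. Added after the data were seen were the RPKM values as deposited, median-of-ratios scaling, scaling without hCG and mitochondrial genes, voom on estimated reads, the embryo as a random effect, list tests without each sum in turn, and leaving out cells under 3 M reads, cells over 15% mitochondrial reads or the second cell of each close pair.

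The fits were tested on simulated data with 200 of 13990 genes changed. At a log2 change of 2, recovery was 70.1% for STB against CTB over both days, 47.8% at day 10, 38.8% at day 12 and 10.4% for the difference between the days. It was 11.9% for MTB against CTB, 7.46% for MTB against STB, 59.7%, 53.7% and 49.3% for CTB of day 10 against 8, 12 against 10 and 12 against 8, and 31.3% for STB between days. Recovery at a log2 change of 4 was 93.9, 97.0, 87.9, 69.7, 77.3, 68.2, 100.0, 98.5, 98.5 and 86.4% in the same order. With the embryo as a block, recovery at a log2 change of 2 was 44.8% over both days, 5.97% at day 10 and 0% at day 12, for the difference and in both MTB comparisons, and at a log2 change of 4 it was 97.0, 86.4, 36.4, 3.03, 0 and 0% in that order. Real data gave block calls for MTB, so these rates cannot weigh calls the block lost. Camera found 10 of 10 shifted lists and 1 of 20 unshifted ones. That rate was untested for correlated genes. R 4.3.3, the data.table package (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.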

Results

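The data were RNA profiles of single trophoblast cells from human embryos kept in extended culture, in which a blastocyst goes on developing in a dish past the stage at which it would implant. The submitters named the lineage of each cell. Cytotrophoblast (CTB) is the mononuclear precursor layer, syncytiotrophoblast (STB) is the multinucleated syncytium, and migratory trophoblast (MTB) is the population that moves away from the embryo. The values of 135 cells were analysed. Day 8 gave 26 CTB cells from 4 embryos and 2 STB cells from 1 embryo. Day 10 gave 27 CTB cells from 4 embryos and 20 STB cells from 3 embryos. Day 12 gave 32 CTB cells from 3 embryos, 12 STB cells from 2 embryos, 12 MTB cells from 1 embryo and 4 MTB cells without an embryo number. The embryo was the replicate, so cells were averaged by embryo and lineage into 18 sums in 7 groups. Levels below are CPM, as the mean ± SD over embryos, and log2 fold changes carry their standard error.

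Genes of chorionic gonadotropin (hCG), the hormone that maintains early pregnancy, took a share of the reads that differed between groups. The median over cells of the share of listed reads was 0.432% in day 8 CTB, 22.7% in day 10 CTB, 11.2% in day 12 CTB, 39.5% in day 10 STB, 39.1% in day 12 STB and 4.20% in MTB. CGA, its alpha subunit gene on chromosome 6, 87085498 to 87095406 of hg38, stood at 17754 ± 21376 in day 8 CTB (n = 4), 106106 ± 23316 in day 10 CTB (n = 4) and 158658 ± 43703 in day 10 STB (n = 3). Coordinates are whole gene spans.

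**Figure D1:**
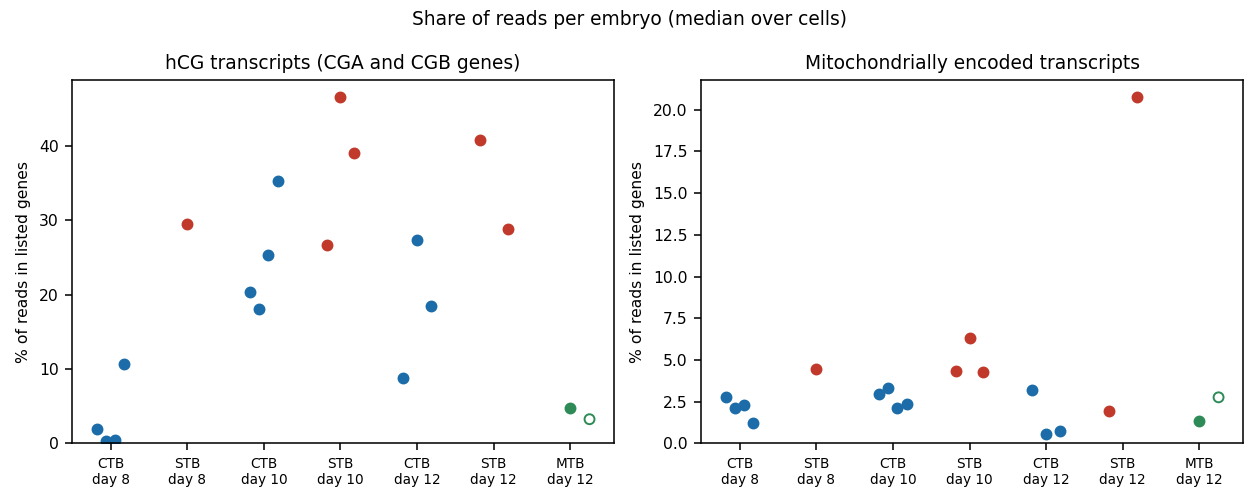
Percent of the reads of listed genes that fell on hCG genes and on mitochondrially encoded genes, as the median over the cells of each embryo, by day and lineage. The hCG share was 0.298 to 10.7% in the 4 day 8 CTB embryos and 26.7 to 46.5% in the 3 day 10 STB embryos, and the mitochondrial share was 20.8% in embryo 6 of day 12 STB.

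STB was compared with CTB to see what set the syncytium apart. Averaged over days 10 and 12, 20 of 25 S phase genes and 11 of 28 hypoxia and glycolysis genes fell in STB, and 10 of 13 mitochondrially encoded genes rose. These lists passed camera at a preset correlation, and none with an estimated correlation (adjusted p = 0.358, 0.593 and 0.236). KRT7, a keratin of simple epithelia (chromosome 12, 52232520 to 52252186), was 484 ± 172 in CTB and 129.7 ± 81.1 in STB at day 10 (n = 4 and 3), and 1219 ± 1004 and 123 ± 52.3 at day 12 (n = 3 and 2). Its log2 fold change was -2.53 ± 0.43 (limma adjusted p = 0.00214). CDH1, the epithelial cadherin (chromosome 16, 68737225 to 68835548), fell (-2.59 ± 0.51, adjusted p = 0.00443). In CTB and STB it was 114 ± 25.3 and 6.67 ± 2.98 at day 12, with overlap at day 10 (8.00 to 53.5, 8.52 to 19.3).

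By count of lower genes, the lists of S phase and of G2 and M phase came first. Of 25 tested S phase genes, 20 fell, none rose and 5 did not pass. The number was 22 adjusted over the list alone. MCM2, a subunit of the replicative helicase, went from 34.1 ± 20.9 in CTB to 12.3 ± 5.87 in STB at day 10 and from 96.8 ± 26.3 to 10.2 ± 7.30 at day 12 (-2.26 ± 0.42, adjusted p = 0.00307). The median of the list was -1.63 (camera adjusted p = 3.04e-10, and adjusted p = 0.358 with an estimated correlation). Of 30 G2 and M phase genes, 13 fell, or 17 adjusted over the list alone, among them the cyclin gene CCNA2 (-2.33 ± 0.42, adjusted p = 0.00253). Their median was -1.22 (camera adjusted p = 2.52e-04, and adjusted p = 0.593 with an estimated correlation). With median-of-ratios scaling 10 S phase and 2 G2 and M phase genes fell. The counts were 12 and 5 without day 12 STB of embryo 6. For G2 and M phase 6 fell without day 12 STB of embryo 4, where the list call was lost (adjusted p = 0.235), and 7 without day 10 STB of embryo 2. The 17 were 10 in the former case.

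Of 28 hypoxia and glycolysis genes, 11 fell, or 14 adjusted over the list alone, with a median of -1.03 (camera adjusted p = 0.00459, and adjusted p = 0.593 with an estimated correlation). The count was 3 without day 12 STB of embryo 6. The list call was lost without day 12 STB of embryo 4 (adjusted p = 0.0791). PKM (-2.04 ± 0.33, adjusted p = 0.00163) and PFKP (-2.44 ± 0.35, adjusted p = 9.05e-04), both glycolytic enzymes, were among the fallen members. Of 13 mitochondrially encoded genes, which specify respiratory chain subunits, 10 rose, or 12 adjusted over the list alone, with a median of 1.87 (camera adjusted p = 7.73e-22, and adjusted p = 0.236 with an estimated correlation). MT-ND2 was 842 ± 195 in CTB and 2569 ± 480.3 in STB at day 10, and changed by 2.61 ± 0.50, adjusted p = 0.00373. The mitochondrial share of listed reads was 4.28 to 6.34% in the day 10 STB embryos and 2.13 to 3.33% in day 10 CTB. At day 12 it was 1.92% in STB of embryo 4 and 20.8% in STB of embryo 6, against 0.556 to 3.17% in CTB. When day 12 STB of embryo 6 was left out, 2 of the 13 rose, or 6 adjusted over the list alone, and the median was 1.25, and 6 rose without day 10 STB of embryo 2. Without cells over 15% mitochondrial reads, 7 rose. Nuclear genes of oxidative phosphorylation went both ways, 4 of 49 higher and 8 lower both over all genes and adjusted over the list alone, with a mean near 0 (camera adjusted p = 1.32e-05 for higher, and adjusted p = 0.593 with an estimated correlation). Of these genes 0 were higher and 1 lower without day 12 STB of embryo 6, and 0 and 4 without day 10 STB of embryo 2. The higher count was 1 or 2 without day 10 STB of embryo 1, day 10 CTB of embryo 2 or 3, or day 12 CTB of embryo 4 or 6.

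None of 19 tested placental hormone genes and none of 9 pregnancy-specific glycoprotein genes passed singly, by limma over all genes or adjusted over the list alone. Their medians were 0.36 (camera adjusted p = 2.09e-04 for higher) and 0.16 (camera adjusted p = 0.0151 for higher), and both had adjusted p = 0.593 with an estimated correlation. The medians without day 12 STB of embryo 6 were 0.81 (adjusted p = 8.10e-09) and 1.49 (adjusted p = 4.84e-08). That of hormones was 0.19 without day 12 CTB of embryo 3 (adjusted p = 0.0178). Both calls were lost without day 12 STB of embryo 4, with medians of -0.10 (adjusted p = 0.251) and -1.10 (adjusted p = 0.988). The median of hormones was 0.55 and 0.70 without day 10 STB and day 12 CTB of embryo 4. The glycoprotein call was lost with median-of-ratios scaling (adjusted p = 0.182) and without day 12 CTB of embryo 3, where the median was -0.27 (adjusted p = 0.127), day 10 CTB of embryo 1 (-0.13, adjusted p = 0.0550) and day 10 STB of embryo 2 (-0.19, adjusted p = 0.126). Its median moved by over 1.5 times without each other sum. CGA changed by 0.79 ± 0.77, adjusted p = 0.493, ERVW-1, the syncytin-1 gene (chromosome 7, 92468380 to 92477986), by 0.04 ± 0.45, adjusted p = 0.954, and the syndecan gene SDC1 (chromosome 2, 20200797 to 20225433) by -0.51 ± 0.58, adjusted p = 0.556. ERVW-1 was 498 ± 198 in CTB and 494 ± 85.2 in STB at day 10. Of 30 genes of endoplasmic reticulum stress and secretion, 1 rose over all genes and none adjusted over the list alone (camera adjusted p = 0.00153 for higher, and adjusted p = 0.593 with an estimated correlation). Their median was -0.15, opposite in sign to the test, 0.48 with median-of-ratios scaling, 0.21 without day 12 STB of embryo 6 and -0.44 without day 12 CTB of embryo 3. The call was lost without day 12 STB of embryo 4 (adjusted p = 0.315), with 5 genes lower and a median of -0.38. The member was SPCS3, a signal peptidase subunit (0.94 ± 0.32, adjusted p = 0.0495, and adjusted p = 0.0806 with the embryo as a block), a call lost without any of the 12 sums but D10 CTB of embryo 4.

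For the other lists camera gave no call, and each held at most 7 changed genes, all lower in STB. The lower genes without day 12 STB of embryo 6 were 3 for early response, 3 for cytotrophoblast, 1 for pan-trophoblast and 2 for matrix genes. There the lists of early response, cytotrophoblast and epithelial-mesenchymal transition passed (adjusted p = 0.0148, 0.0463 and 0.0179). Without day 10 STB of embryo 2, 3 early response and 2 matrix genes were lower. Early response also passed without day 10 CTB of embryo 1, day 10 STB of embryo 4 or day 12 CTB of embryo 3 (adjusted p = 0.0184, 0.0293 and 0.0258). Genes of early response and heat shock had 7 of 21 lower, 9 adjusted over the list alone, and their camera test passed with the embryo as a block (adjusted p = 0.0826 without and 0.0153 with it). Cytotrophoblast genes had 6 of 19 lower and 6 adjusted over the list alone. Pan-trophoblast genes had 2 of 12 lower, KRT7 and the transcription factor gene GATA3 (-1.06 ± 0.26, adjusted p = 0.0127), and 6 adjusted over the list alone. Syncytin and fusion genes had 3 of 18 lower and 3 adjusted over the list alone. Extravillous trophoblast genes had 6 of 20 lower and 9 adjusted over the list alone. Epithelial-mesenchymal transition genes had 3 of 12 lower and 5 adjusted over the list alone. Matrix protease and basement membrane genes had 4 of 22 lower and 5 adjusted over the list alone, the latter 3 without day 10 STB of embryo 2. Of the counts over the list alone, that of pan-trophoblast was 2 or 3 without day 10 CTB of embryo 1, 2 or 3, day 10 STB of embryo 2 or day 12 STB of embryo 6, and that of extravillous genes 5 without day 12 CTB of embryo 3. That of transition genes was 3 without day 12 CTB of embryo 3 or day 12 STB of embryo 4, and 8 without day 10 CTB of embryo 4 or day 12 STB of embryo 6.

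Interferon-stimulated genes had 5 of 38 lower, 5 adjusted over the list alone, the latter between 0 and 14 without single sums (0 without day 12 STB of embryo 4, for example, and 14 without day 12 CTB of embryo 4). Over all genes 1 fell without either day 12 STB sum, and 2 or 3 without day 10 CTB of embryo 1 or 3 or day 10 STB of embryo 2 or 4. The number was 9 without day 10 CTB of embryo 4, and 11 without day 12 CTB of embryo 4, where the list passed (adjusted p = 0.0270). ISG15, an interferon-induced ubiquitin-like protein gene (chromosome 1, 1001138 to 1014541), did not pass (-0.84 ± 0.53, adjusted p = 0.281), nor did IFI27 (-0.69 ± 0.55, adjusted p = 0.399). CDK inhibitors and senescence genes had 2 of 15 lower and 3 adjusted over the list alone, and this list passed with the embryo as a block (adjusted p = 0.0493 against 0.240 without it). Both counts were 5 without day 10 CTB of embryo 4, and 1 without any other day 10 sum or day 12 STB of embryo 6. Lists of steroid and cholesterol synthesis, solute transporters, imprinted genes, interferon ligands and receptors, and WNT, BMP and FGF signalling held 1 to 3 lower genes each, or 1 to 6 adjusted over the list alone. Without day 12 STB of embryo 6 each held at most 1 over all genes, and without any other sum at most 5. Among markers of other cell types, no member passed of 3 epiblast (median -0.31), 7 hypoblast (median -0.32, and 0.12 when scaled without hCG and mitochondrial genes) or 4 amnion and mesenchyme genes (median 0.05). Of 4 immune, endothelial and blood markers 2 were lower, CD68 and PECAM1, and 3 adjusted over the list alone (median -1.55).

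By limma, 2246 of 13990 genes passed in this comparison, 91 higher and 2155 lower in STB (95.9% lower), and the median of all genes was -0.46. Camera calls are relative to that median. The direction of the split depended on the scaling, with 608 higher and 429 lower (41.4% lower, all-gene median -0.02) by median-of-ratios, 544 and 398 (42.3%, -0.01) after quantile normalization, and 271 and 590 (68.5%, -0.13) when scaled without hCG and mitochondrial genes. KRT7, CDH1, MCM2, CCNA2, PKM, PFKP and MT-ND2 passed under all 3, while GATA3 passed under none of them. The count was 1207 without day 10 STB of embryo 2 and 594 without day 12 STB of embryo 6.

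**Figure D2:**
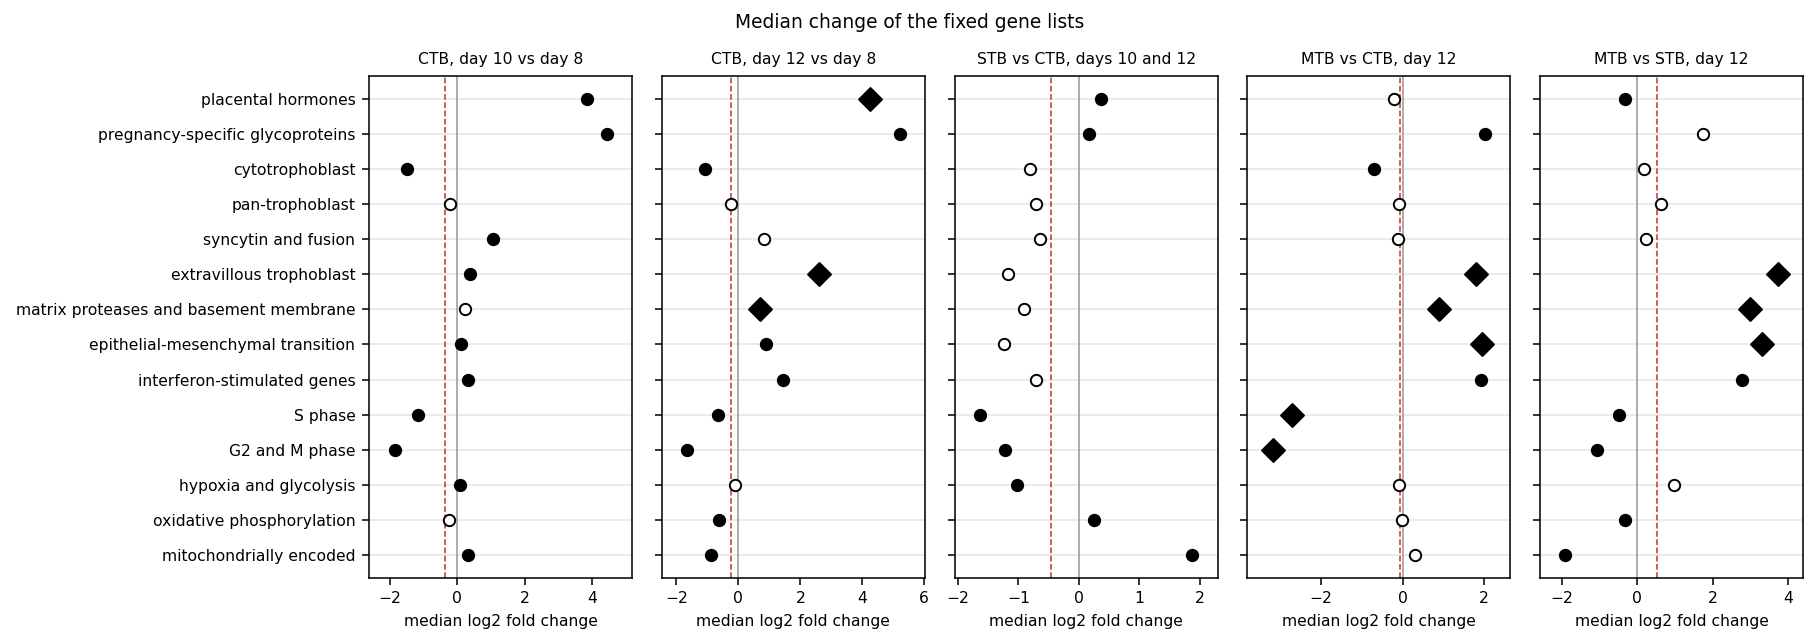
Median log2 fold change of the fixed gene lists in 5 comparisons (x axis, log2), filled where camera passed at the preset correlation and as a diamond where it also passed with an estimated correlation, with the all-gene median as a dashed red line. The S phase list lay at -1.63 in STB against CTB and at -2.71 in MTB against CTB, and placental hormones at 3.84 in CTB between days 8 and 10, each on the scale of CPM.

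Within single days the same lineage comparison had less material. At day 10, with 3 STB and 4 CTB embryos, KRT7 changed by -2.02 ± 0.56, adjusted p = 0.223, CDH1 by -1.24 ± 0.66, adjusted p = 0.518 and MKI67, a proliferation marker (chromosome 10, 128096659 to 128126385), by -0.95 ± 0.66, adjusted p = 0.640. Limma called 1 gene, the clone-named AL157871.1, higher in STB (5.78 ± 3.22 against 0.409 ± 0.353, log2 fold change 2.19 ± 0.33, adjusted p = 0.0448), and 1502 genes had an unadjusted p under 0.05. It was lost with the embryo as a block (adjusted p = 0.425), and the count was 0 without any of the CTB sums or the STB sums of embryos 2 and 4, and 2 without that of embryo 1. The all-gene median was -0.28, and 0.01 with median-of-ratios scaling. None of 25 S phase genes passed over all genes or adjusted over the list alone (median -0.94, or -0.58 without STB of embryo 2, camera adjusted p = 6.45e-06, and adjusted p = 0.351 with an estimated correlation). Over the list alone 15 fell without CTB of embryo 4 and 5 without STB of embryo 1. Of the mitochondrially encoded genes 6 of 13 rose adjusted over the list alone and none over all genes (median 1.44, camera adjusted p = 8.21e-15, and adjusted p = 0.274 with an estimated correlation). The count was 4 without STB of embryo 1 and 0 without any other sum. Early response and heat shock genes had 7 of 21 lower adjusted over the list alone and none over all genes (median -0.95, camera adjusted p = 8.82e-05, and adjusted p = 0.169 with an estimated correlation), or 3 without STB of embryo 1 or 2 and 2 without CTB of embryo 3.

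At day 12, with 2 and 3 embryos, 14 of 25 S phase, 7 of 30 G2 and M phase, and 8 of 28 hypoxia and glycolysis genes fell in STB. These lists passed camera at a preset correlation, and none with an estimated correlation (adjusted p = 0.285, 0.635 and 0.635). The latter pair also lost their calls with the embryo as a block (adjusted p = 0.0968 and 0.0905) and without CTB of embryo 3 (adjusted p = 0.0589 and 0.0595). SERPINB9, a granzyme B inhibitor, was 511 ± 313 in CTB and 18.4 ± 5.48 in STB (-4.48 ± 0.84, adjusted p = 0.00855), and CDH1 changed by -3.94 ± 0.79, adjusted p = 0.0102. Of 25 S phase genes 14 fell, or 21 adjusted over the list alone, with a median of -2.27 (camera adjusted p = 2.78e-11, and adjusted p = 0.285 with an estimated correlation). Of 20 extravillous trophoblast genes 5 fell, or 10 adjusted over the list alone, and the list did not pass (median -1.84, camera adjusted p = 0.0628), though it did with median-of-ratios scaling (adjusted p = 0.0301) and without CTB of embryo 4 or 6 (adjusted p = 0.0299 and 0.0119). Without STB of embryo 4, 9 S phase and 3 extravillous genes fell, the latter also without CTB of embryo 3 or 6. The 10 extravillous genes over the list alone were 4 without CTB of embryo 3 and 6 without STB of embryo 6. HLA-G, a nonclassical HLA gene of invasive trophoblast (chromosome 6, 29826967 to 29831125), changed by -3.47 ± 0.83, adjusted p = 0.0197, and NOTUM, a WNT deacylase gene, by -3.89 ± 0.84, adjusted p = 0.0131. Of 38 interferon-stimulated genes 2 fell, or 7 adjusted over the list alone, and the list itself did not pass (median -1.07, camera adjusted p = 0.152), though it did without CTB of embryo 4, with 7 genes lower, and of embryo 6 (adjusted p = 5.67e-04 and 0.0163). The 7 adjusted over the list alone were 1, 14 and 1 without CTB of embryos 3, 4 and 6 and 0 without either STB sum.

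Of 13 mitochondrially encoded genes 5 rose at day 12, or 12 adjusted over the list alone (median 2.15, camera adjusted p = 9.32e-21, and adjusted p = 0.272 with an estimated correlation), and without STB of embryo 6, whose mitochondrial share was 20.8%, none rose either way and the median was 1.15. The count was 12 without STB of embryo 4 (median 3.49) and 12, 2 and 1 without CTB of embryos 3, 4 and 6, or 13, 5 and 7 adjusted over the list alone. Of 30 G2 and M phase genes 7 fell, or 18 adjusted over the list alone (camera adjusted p = 9.03e-05, and adjusted p = 0.635 with an estimated correlation). Of 28 hypoxia and glycolysis genes 8 fell, or 12 adjusted over the list alone (camera adjusted p = 0.0264, and adjusted p = 0.635 with an estimated correlation). The lower G2 and M phase genes were 1, 4 and 11 without CTB of embryos 3, 4 and 6 and 2 without STB of embryo 4, where the list call was lost (adjusted p = 0.495). Over the list alone they were 4, 10 and 2 without CTB of embryos 3 and 4 and STB of embryo 4, and the hypoxia and glycolysis count was 1 without STB of embryo 6. The hypoxia and glycolysis call was lost without STB or CTB of embryo 4 (adjusted p = 0.310 and 0.0806), and 3 fell without CTB of embryo 3. With the embryo as a block the camera tests of placental hormones and pregnancy-specific glycoproteins, of which none passed singly, gave adjusted p = 0.0624 and 0.106 against 1.77e-04 and 0.00316 without it. Neither call held with an estimated correlation (adjusted p = 0.635 for both). Both were lost too without STB of embryo 4 (adjusted p = 0.533 and 0.882) or CTB of embryo 3 (adjusted p = 0.118 and 0.173). Limma called 18 genes higher and 1106 lower (98.4% lower, all-gene median -0.64), 72 and 75 with median-of-ratios scaling (51.0%, -0.05), 20 and 118 without hCG and mitochondrial genes in the scaling (85.5%, -0.22), and 0 after quantile normalization. The count was 636 without CTB of embryo 3, 440 without that of embryo 6, 1722 without STB of embryo 4 and 0 without that of embryo 6, so every gene named here was lost without the last.

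The difference between the days was tested directly. No gene passed in limma, 581 had an unadjusted p under 0.05, the smallest adjusted p was 0.994, and voom on estimated reads also gave 0. The all-gene median was -0.35, and -0.02 with median-of-ratios scaling. HLA-G differed by -3.49 ± 1.08, adjusted p = 0.994. Camera passed for 11 of 24 lists, none of which held with an estimated correlation, where the smallest adjusted p was 0.293. The S phase list had a median of -1.36 (adjusted p = 1.58e-07), extravillous trophoblast genes -1.498 (adjusted p = 0.00182) and interferon-stimulated genes -0.91 (adjusted p = 0.0217). The latter pair without day 12 CTB of embryo 3 had medians of -1.08 and -0.30 (adjusted p = 0.0811 and 0.977), and with the embryo as a block interferon-stimulated genes had adjusted p = 0.994. The interferon call was also lost without day 10 CTB of embryo 4, day 10 STB of embryo 2 or day 12 STB of embryo 4 (adjusted p = 0.103, 0.108 and 0.320).

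MTB was compared with CTB and STB of day 12, to ask what marks the cells that leave the embryo, interferon-response genes included. The numbered MTB cells came from 1 embryo, so their sum was assumed to vary between embryos like those of the other groups. Against CTB, 4 of 22 matrix protease and basement membrane genes rose in MTB and 8 of 25 S phase genes fell, lists whose camera calls held with an estimated correlation (adjusted p = 0.00655 for both). AOC1, which encodes the histamine-degrading diamine oxidase (chromosome 7, 150824627 to 150861504), was 213 in MTB and 0.666 ± 0.904 in the 3 CTB embryos (7.13 ± 0.75, adjusted p = 9.86e-05), and 5 of 12 MTB cells had at least 10 CPM of it. MMP3, a matrix metalloproteinase gene, was 418 and 3.52 ± 5.96 (7.47 ± 0.98, adjusted p = 0.00145), while AOC1 and MMP3 stood at 0.402 and 3.72 in the MTB cells without an embryo number. With those cells as a second replicate both calls were lost (adjusted p = 0.171 and 0.0862). SERPINE2, a serine protease inhibitor gene, was 1257 and 20.2 ± 8.34 (5.96 ± 0.91, adjusted p = 0.00289). RRM2, a ribonucleotide reductase subunit gene, was 10.1 in MTB against 1324 ± 804 in CTB (-6.73 ± 0.97, adjusted p = 0.00241).

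Of 22 matrix protease and basement membrane genes 4 rose in MTB over CTB, or 8 adjusted over the list alone, with a median of 0.89 (camera adjusted p = 1.91e-09, and 0.00655 with an estimated correlation), the 8 being 5 without CTB of embryo 3. The urokinase receptor gene PLAUR rose by 5.79 ± 0.99, adjusted p = 0.00752. Of 20 extravillous trophoblast genes 2 rose, AOC1 and the metalloproteinase gene PAPPA (3.65 ± 0.60, adjusted p = 0.00575), or 6 adjusted over the list alone (median 1.79, camera adjusted p = 1.34e-11, and adjusted p = 0.00760 with an estimated correlation), with 5 higher without CTB of embryo 3. Of 12 epithelial-mesenchymal transition genes none rose over all genes and 5 adjusted over the list alone (median 1.96, camera adjusted p = 9.34e-10, and adjusted p = 0.0110 with an estimated correlation), or 3 without CTB of embryo 6. HLA-G was 813 in MTB and 289 ± 282 in CTB. It did not pass (2.15 ± 1.05, adjusted p = 0.815) and passed with the embryo as a block (3.79, adjusted p = 0.0294). KRT7 behaved likewise, at 4641 against 1219 ± 1004 (2.24 ± 0.84, adjusted p = 0.479, and 3.27, adjusted p = 0.0464 with the block), and both were highest among the CTB embryos in embryo 3.

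Of 25 S phase genes 8 fell in MTB, or 19 adjusted over the list alone, and of 30 G2 and M phase genes 5 fell, or 24 adjusted over the list alone. Their medians were -2.71 and -3.19 (camera adjusted p = 2.51e-36 and 1.34e-33, and adjusted p = 0.00655 and 0.0368 with an estimated correlation). Without CTB of embryo 4, 5 S phase genes fell, and the G2 and M phase count was 1, 1 and 10 without CTB of embryos 3, 4 and 6. The replication licensing gene CDC6 (-4.76 ± 0.66, adjusted p = 0.00209) and the mitotic gene BIRC5 (-4.34 ± 0.74, adjusted p = 0.00752) were among them. MKI67 missed the threshold (-4.16 ± 0.995, adjusted p = 0.0676), and 0 of 16 MTB cells reached 10 CPM of it, against 21 of 24 CTB cells of embryo 3, 1 of 4 of embryo 4 and 1 of 4 of embryo 6. CDKN2B, a CDK inhibitor gene, rose (2.87 ± 0.55, adjusted p = 0.0160), with adjusted p = 0.0628 under the block, 0.0584 without CTB of embryo 4 and 0.430 with the unnumbered cells as a second replicate. Its list of 15 had 1 gene higher, or 3 adjusted over the list alone (camera adjusted p = 0.0472, adjusted p = 0.193 with an estimated correlation, adjusted p = 0.374 with the block, and adjusted p = 0.217 without CTB of embryo 3).

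Interferon-stimulated genes had a median of 1.92 in MTB over CTB (camera adjusted p = 2.94e-14, and adjusted p = 0.102 with an estimated correlation). None of the 38 rose over all genes, 7 rose adjusted over the list alone (21, 1 and 0 without CTB of embryos 3, 4 and 6), 8 over all genes with the embryo as a block and 4 without CTB of embryo 3. IFI27, an interferon-induced gene on chromosome 14, 94104836 to 94116698, was 147 in MTB and 13.5 ± 20.8 in CTB (4.67 ± 1.08, adjusted p = 0.0539, and 6.25, adjusted p = 0.00497 with the block). It reached 10 CPM in 4 of 12 numbered MTB cells, 2 of the 4 unnumbered, 11 of 24 CTB cells of embryo 3 and 0 of 8 CTB cells of the other day 12 embryos. Interferon ligands and receptors had a median of 1.19 with no gene passing, over all genes or the list alone (camera adjusted p = 0.00656, and adjusted p = 0.105 with an estimated correlation). Pregnancy-specific glycoproteins had a median of 2.02 (camera adjusted p = 0.00401, and adjusted p = 0.527 with an estimated correlation), which was 0.02 with the block (adjusted p = 0.648), and the call was lost without CTB of embryo 3 (adjusted p = 0.138). Placental hormones, at -0.20, passed with the block only (-1.70, adjusted p = 2.76e-05). The block also passed mitochondrially encoded genes (1.69, adjusted p = 1.41e-06, against 0.215 without it), which also passed without CTB of embryo 3 (adjusted p = 3.34e-04). Limma called 50 genes higher and 37 lower (42.5% lower, all-gene median -0.07), 91 and 43 with median-of-ratios scaling (32.1%, 0.05), and 117 and 28 with the embryo as a block. The count was 44 without CTB of embryo 4.

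Against STB of day 12 (2 embryos), under the same assumption for the 1 MTB sum, 10 of 20 extravillous trophoblast, 6 of 22 matrix and 11 of 38 interferon-stimulated genes rose in MTB. The calls of the first pair of lists held with an estimated correlation, and that of interferon-stimulated genes did not (adjusted p = 0.178). KRT7 was 4641 in MTB and 123 ± 52.3 in STB (5.29 ± 0.89, adjusted p = 0.00510), and SPARC, a matricellular glycoprotein gene, 776 and 14.1 ± 5.02 (5.73 ± 0.91, adjusted p = 0.00322). The 10 extravillous genes, or 15 adjusted over the list alone, belonged to a list with a median of 3.73 (camera adjusted p = 2.14e-11, and 0.0119 with an estimated correlation), HLA-G among them (5.62 ± 1.11, adjusted p = 0.0120). Of 22 matrix genes 6 rose, or 14 adjusted over the list alone (median 2.99, camera adjusted p = 2.31e-09, and adjusted p = 0.00876 with an estimated correlation). Of 12 epithelial-mesenchymal transition genes 6 rose both ways, FN1, the fibronectin gene, by 5.88 ± 1.12, adjusted p = 0.0103 (list median 3.30, camera adjusted p = 1.26e-07, and adjusted p = 0.0368 with an estimated correlation). Without STB of embryo 6, 2 extravillous, 3 matrix and 2 transition genes rose.

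Of 38 interferon-stimulated genes 11 rose in MTB over STB, or 26 adjusted over the list alone, with a median of 2.78 (camera adjusted p = 2.14e-11, and adjusted p = 0.178 with an estimated correlation). Without STB of embryo 6 none of the 38 rose, or 18 adjusted over the list alone. IFI27 changed by 6.17 ± 1.14, adjusted p = 0.00866 and IFIT1, which binds viral RNA, by 6.15 ± 1.33, adjusted p = 0.01999. IFNGR2, a chain of the interferon gamma receptor, was the 1 of 11 ligand and receptor genes that rose (4.36 ± 1.09, adjusted p = 0.0419), or 6 adjusted over the list alone (list camera adjusted p = 0.00188, and adjusted p = 0.108 with an estimated correlation), and 5 rose without STB of embryo 4, or 0 adjusted over the list alone without that of embryo 6. Of 15 CDK inhibitor and senescence genes 3 rose, or 4 adjusted over the list alone, such as CDKN2B (3.76 ± 0.58, adjusted p = 0.00255) (list camera adjusted p = 0.0271, and adjusted p = 0.178 with an estimated correlation). Without STB of embryo 6, 1 rose, and without that of embryo 4 the list call was lost (adjusted p = 0.0730). The 13 mitochondrially encoded genes had a median of -1.91 with none passing (camera adjusted p = 2.14e-11, and adjusted p = 0.178 with an estimated correlation), and of -0.80 without STB of embryo 6 (adjusted p = 3.98e-05) and -2.93 without that of embryo 4. Limma called 325 genes higher and 3 lower (0.915% lower, all-gene median 0.52, and 0.03 with median-of-ratios scaling, where 199 were higher and 12 lower). The count was 947 without STB of embryo 4 and 34 without that of embryo 6, which kept AOC1, MMP3, PLAUR, SERPINE2, KRT7, SPARC, CDKN2B and NOTUM but ended the HLA-G, FN1, IFI27, IFIT1 and IFNGR2 calls. With the unnumbered cells as a second replicate the AOC1, CDKN2B and IFIT1 calls were lost (adjusted p = 0.0903, 0.0595 and 0.182).

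**Figure D3:**
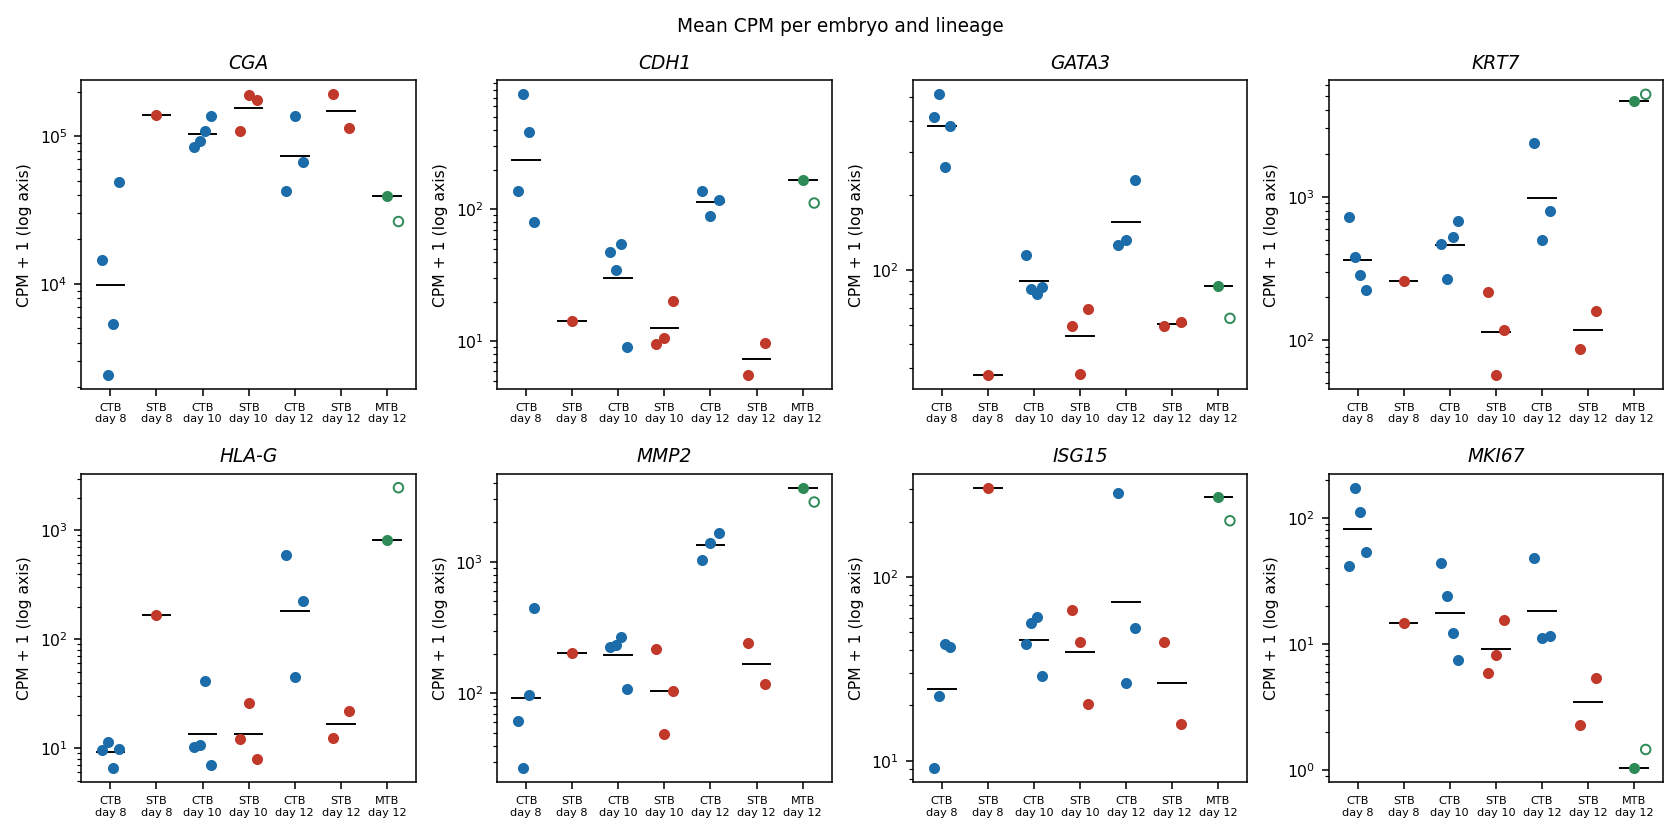
CPM plus 1 (log axis) of CGA, CDH1, GATA3, KRT7, HLA-G, MMP2, ISG15 and MKI67 in each embryo, by day and lineage, with bars at the geometric mean and an open circle for the MTB cells without an embryo number. HLA-G was 813 in numbered MTB, 2473 in the unnumbered cells and 44.4 to 597 in the 3 day 12 CTB embryos.

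The 4 MTB cells without an embryo number were set against the same CTB embryos. Of the 87 genes called between numbered MTB and CTB, 81 differed in the same direction (93.1%), 44 of the 50 higher and 37 of the 37 lower, against 71.2% of all genes. Unchanged groups simulated against these controls gave 58.0% on average, between 46.0 and 70.1% in 100 simulations. Over all genes the covariance of the fold changes was 0.605 against 0.144 in the simulations, a difference of 0.462. The 3 controls are too few to be split, so part of the excess may come from the shared controls. The unnumbered cells had 2473 CPM of HLA-G, 90.3 of IFI27 and 201 of ISG15, and 0 of 4 had 10 CPM of AOC1 or MMP3, against 5 and 8 of the 12 numbered cells.

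CTB was compared between days to follow the precursor layer through extended culture. From day 8 to day 10 (4 embryos each), 15 of 19 placental hormone genes rose, and 20 of 30 G2 and M phase and 7 of 19 cytotrophoblast genes fell. These lists passed camera at a preset correlation, and none with an estimated correlation (adjusted p = 0.0767, 0.247 and 0.240). CSH2, a placental lactogen gene, went from 3.95 ± 3.34 to 611 ± 393 (7.02 ± 0.997, adjusted p = 0.00119), PSG3 from 2.38 ± 2.75 to 348 ± 361 (6.39 ± 0.98, adjusted p = 0.00182), and TFPI, which encodes the tissue factor pathway inhibitor (chromosome 2, 187464230 to 187565760), from 8.29 ± 7.25 to 395 ± 90.8 (5.75 ± 0.51, adjusted p = 1.21e-05). DNMT3L, a cofactor of de novo DNA methylation (chromosome 21, 44246339 to 44262216), went from 387 ± 149 to 14.4 ± 7.71 (-4.73 ± 0.63, adjusted p = 7.12e-04).

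Of 19 placental hormone genes 15 rose from day 8 to day 10, both ways of adjusting, with a median of 3.84 (camera adjusted p = 3.57e-21, and adjusted p = 0.0767 with an estimated correlation). The CGB, PSG and CSH genes are near-identical copies that can share reads, so their single values are uncertain. Of 9 pregnancy-specific glycoproteins 5 rose, or 8 adjusted over the list alone (median 4.43, camera adjusted p = 6.75e-11, and adjusted p = 0.141 with an estimated correlation). Of 30 genes of endoplasmic reticulum stress and secretion 6 rose, or 7 adjusted over the list alone (camera adjusted p = 9.48e-10, and adjusted p = 0.155 with an estimated correlation), led by CHAC1, a glutathione-degrading enzyme of the stress response (4.597 ± 0.73, adjusted p = 0.00219). The count over all genes was 3 without day 10 embryo 1 and 1 without day 10 embryo 2 or 4 or day 8 embryo 2 or 3, each 1 or 3 over the list alone. Of 21 early response and heat shock genes 6 rose over all genes, the stress factor ATF3 by 2.77 ± 0.61, adjusted p = 0.0108, and 6 rose and 2 fell adjusted over the list alone (camera adjusted p = 3.78e-05, and adjusted p = 0.0767 with an estimated correlation). The higher count was 2 or 3 without day 10 embryo 2 or 4 or day 8 embryo 2 or 3, and 3 fell without day 8 embryo 4. Syncytin and fusion genes had 2 of 18 higher and 2 lower, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.00448 for higher, and adjusted p = 0.132 with an estimated correlation). The 2 higher were ERVW-1 and ERVFRD-1, both syncytin genes. The higher count was 0 without day 8 embryo 2 or 3 or day 10 embryo 2 or 4, 1 without day 8 embryo 1 and 5 without day 8 embryo 4, and over the list alone 0, 1 and 3 without day 8 embryo 3 and day 10 embryos 4 and 2. The lower count was 0 or 1 without any sum but day 10 embryo 3 or day 8 embryo 4. Of 13 steroid synthesis genes 4 rose and 2 fell both ways, with a negative median, opposite in sign to the test (camera adjusted p = 0.0469 for higher, and adjusted p = 0.247 with an estimated correlation). This call was lost without any sum but those of embryo 4 (adjusted p = 0.0547 to 0.0776). The higher count was 2 without day 10 embryo 2 or 4 or day 8 embryo 1, 2 or 3.

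Of 30 G2 and M phase genes 20 fell from day 8 to day 10, or 27 adjusted over the list alone, with a median of -1.85 (camera adjusted p = 9.48e-10, and adjusted p = 0.247 with an estimated correlation), and 4 fell with median-of-ratios scaling. The count was 4 and 1 without day 10 embryos 2 and 4, and 12, 4 and 5 without day 8 embryos 1, 2 and 3. MKI67 reached 10 CPM in 21 of 26 CTB cells at day 8 and 12 of 27 at day 10. Of 25 S phase genes 9 fell, or 12 adjusted over the list alone (camera adjusted p = 4.62e-04, and adjusted p = 0.311 with an estimated correlation). Their count was 3 and 2 without day 10 embryos 2 and 4, and 5, 2, 4 and 14 without day 8 embryos 1, 2, 3 and 4. Over the list alone 7 fell without day 10 embryo 4. Of 19 cytotrophoblast genes 7 fell, or 11 adjusted over the list alone (camera adjusted p = 1.22e-04, and adjusted p = 0.240 with an estimated correlation). Their count was 4 without day 10 embryo 4 or day 8 embryo 2 or 3 (5 or 6 over the list alone), and 12 without day 8 embryo 4. GATA3 (chromosome 10, 8053604 to 8075198) went from 391 ± 103 to 89.7 ± 15.9 (-2.08 ± 0.31, adjusted p = 0.00152).

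Limma called 386 genes higher and 1407 lower from day 8 to day 10 (78.5% lower, all-gene median -0.36), 492 and 316 with median-of-ratios scaling (39.1%, 0.04), 477 and 442 after quantile normalization (48.1%, -0.05), and 454 and 437 without hCG and mitochondrial genes in the scaling (49.0%, -0.09). The count was 674 and 528 without day 10 sums of embryos 2 and 4, and 1045, 458, 696 and 3011 without day 8 sums of embryos 1, 2, 3 and 4. Embryo 4 of day 8 held 2 cells and had an hCG share of 10.7%. CSH2, PSG3, TFPI, CHAC1, DNMT3L and GATA3 passed without each of the 8 sums in turn, while MKI67 did not (-2.21 ± 0.61, adjusted p = 0.0272, adjusted p = 0.0978 without day 8 embryo 2).

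From day 10 to day 12 of CTB (4 and 3 embryos), 2 genes passed, both higher. GM2A, a cofactor of ganglioside breakdown (chromosome 5, 151212150 to 151270440), went from 19.6 ± 7.59 to 174 ± 105 (3.00 ± 0.42, adjusted p = 0.0120), and NOTUM (chromosome 17, 81952507 to 81961840) from 3.12 ± 2.72 to 93.3 ± 73.3 (4.39 ± 0.70, adjusted p = 0.0407). HLA-G missed the threshold (3.78 ± 0.69, adjusted p = 0.0634), at 16.3 ± 16.02 and 289 ± 282, and so did MMP2, which encodes a gelatinase (chromosome 16, 55389700 to 55506691; 2.77 ± 0.69, adjusted p = 0.137). Of 20 extravillous trophoblast genes 1 rose, or 8 adjusted over the list alone (median 1.48, or 0.88 without embryo 3 of day 12, 3 higher without embryo 4, camera adjusted p = 2.69e-08, and adjusted p = 0.0700 with an estimated correlation). Of 38 interferon-stimulated genes none rose over all genes and 7 adjusted over the list alone (median 1.01, camera adjusted p = 2.52e-07, and adjusted p = 0.388 with an estimated correlation), the median was 0.59 without embryo 3 (adjusted p = 0.0401), and 4 rose without embryo 4 of day 12. The 7 were 2 without embryo 3 of day 10 and 1 and 15 without embryos 3 and 4 of day 12. The 13 mitochondrially encoded genes had a median of -1.24, or -2.06 and -0.71 without embryos 3 and 4 of day 12 (camera adjusted p = 2.69e-08, and adjusted p = 0.388 with an estimated correlation), with a mitochondrial share of 3.17% in day 12 CTB of embryo 3 and of 0.556 and 0.761% in embryos 4 and 6. By limma 1737 genes had an unadjusted p under 0.05 (all-gene median 0.15, and 0.02 with median-of-ratios scaling). The count was 12, 1, 12 and 0 without day 10 sums of embryos 1, 2, 3 and 4, and 45 and 0 without day 12 sums of embryos 4 and 6.

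Between day 8 and day 12, 12 of 19 hormone, 11 of 20 extravillous trophoblast and 9 of 38 interferon-stimulated genes rose in CTB. The calls of the first pair of lists held with an estimated correlation, and that of interferon-stimulated genes did not (adjusted p = 0.116). LEP, the leptin gene, went from 5.91 ± 9.36 to 580.2 ± 411 (7.04 ± 0.96, adjusted p = 3.99e-04), HLA-G from 8.33 ± 2.03 to 289 ± 282 (4.32 ± 0.69, adjusted p = 0.00183), and B2M, the light chain of HLA class I, from 7.81 ± 7.79 to 277 ± 282 (4.78 ± 0.88, adjusted p = 0.00497). DNMT3L (-6.08 ± 0.68, adjusted p = 8.71e-05) and the trophectoderm surface gene TACSTD2 (-5.56 ± 0.83, adjusted p = 8.79e-04) fell. Of 19 hormone genes 12 rose, or 17 adjusted over the list alone (median 4.24, camera adjusted p = 3.15e-19, and adjusted p = 0.0404 with an estimated correlation). Of 20 extravillous trophoblast genes 11 rose and 1 fell, or 13 and 1 adjusted over the list alone (median 2.59, or 1.70 without embryo 3 of day 12, camera adjusted p = 1.47e-13, and adjusted p = 0.0111 with an estimated correlation). Of 22 matrix genes 7 rose and 1 fell, or 8 and 1 adjusted over the list alone (camera adjusted p = 2.19e-05, and adjusted p = 0.0404 with an estimated correlation).

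Of 38 interferon-stimulated genes 9 rose between days 8 and 12, or 16 adjusted over the list alone (list median 1.44, camera adjusted p = 1.26e-12, and adjusted p = 0.116 with an estimated correlation). When day 12 embryo 3 was left out, 4 rose and 1 fell, or 9 rose over the list alone, with a median of 0.89. The count was 3 without day 12 embryo 6 and 4, 3 and 5 without day 8 embryos 1, 2 and 3. Of 9 pregnancy-specific glycoproteins 7 rose, or 9 adjusted over the list alone (camera adjusted p = 1.02e-12, and adjusted p = 0.0932 with an estimated correlation). Of 12 epithelial-mesenchymal transition genes 2 rose, or 5 adjusted over the list alone, FN1 by 5.39 ± 0.70, adjusted p = 2.62e-04 (list median 0.89, or 0.19 without embryo 3 of day 12, camera adjusted p = 6.68e-05, and adjusted p = 0.0932 with an estimated correlation). Of 30 G2 and M phase genes 6 fell, or 25 adjusted over the list alone (median -1.65, camera adjusted p = 1.66e-10, and adjusted p = 0.198 with an estimated correlation). The count was 16 without day 12 embryo 3 (median -2.08) and 0 without day 12 embryo 4 or 6. It was 0, 1, 0 and 11 without day 8 embryos 1, 2, 3 and 4. Over the list alone it was 15 without day 12 embryo 4 or day 8 embryo 3 and 0 without day 12 embryo 6. Limma called 375 genes higher and 334 lower (47.1% lower, all-gene median -0.24), 419 and 140 with median-of-ratios scaling (25.04%, 0.05), 384 and 219 after quantile normalization (36.3%, -0.09) and 428 and 169 without hCG and mitochondrial genes in the scaling (28.3%, -0.05). The count was 1227, 313 and 243 without day 12 sums of embryos 3, 4 and 6, and 370, 366, 388 and 1154 without day 8 sums of embryos 1, 2, 3 and 4.

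STB of day 12 was compared with STB of day 10 (2 and 3 embryos), and no gene passed in limma. The smallest adjusted p was 0.131, 725 genes had an unadjusted p under 0.05, and voom on estimated reads also gave 0. CGA was 158658 ± 43703 at day 10 and 153046 ± 55560.3 at day 12 (-0.06 ± 1.19), and KRT7 129.7 ± 81.1 and 123 ± 52.3 (0.06 ± 0.67). PSG3 was 306 ± 237 and 1761 ± 2305, and the 9 pregnancy-specific glycoproteins had a median of 1.94 (camera adjusted p = 5.62e-06, and adjusted p = 0.586 with an estimated correlation), which was 4.55 without embryo 6, 1.17 without day 10 embryo 4 and -0.56 without day 12 embryo 4 (adjusted p = 0.964). None of the 9 rose adjusted over the list alone, or 8 without day 12 embryo 6. The S phase list had a median of -0.75 (camera adjusted p = 1.53e-05, and adjusted p = 0.586 with an estimated correlation), with 2 of 25 lower adjusted over the list alone (9 without day 10 embryo 2 and 0 without day 10 embryo 1 or 4 or day 12 embryo 4), and its call was lost without day 12 embryo 4 (adjusted p = 0.217). The all-gene median was -0.20, and -0.02 with median-of-ratios scaling, and 4 genes passed without the sum of embryo 4.

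The 2 STB cells of day 8 came from embryo 3 and were set against its 8 CTB cells, without a test. Of the 2246 genes called between STB and CTB at days 10 and 12, 2120 differed in the same direction there (94.4%), 77 of the 91 higher and 2043 of the 2155 lower, against 73.9% of all genes, of which 68.7% were lower in the STB sum. CDH1 was 13.1 in day 8 STB, MCM2 8.38, HLA-G 166, ISG15 304 and CGA 139710.0. Of the markers reported in each group, TP63, a transcription factor gene of villous CTB (chromosome 3, 189631416 to 189897279), was 1.47 ± 1.63 in day 8 CTB, 0.769 ± 1.02 in day 10 CTB and 0.0769 ± 0.0640 in day 12 CTB. The hypoblast gene GATA6 (chromosome 18, 22169443 to 22202528) was 8.29 ± 3.87, 6.61 ± 6.81 and 9.75 ± 7.88, and the epiblast gene POU5F1 (chromosome 6, 31164337 to 31180731) 0.103 ± 0.127, 1.33 ± 2.14 and 0.0447 ± 0.0682 in the same groups.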

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

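The tests of mitochondrial reads, of embryo 3 and of scaling without hCG and mitochondrial genes below were chosen after the results were seen, while that of hCG composition by median-of-ratios scaling was written before.

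Among sets of 4 embryos, the gap between an extreme embryo and its neighbour was compared with the range of the set, against the value that chance passes in 1 of 20 sets. In day 8 CTB the highest embryo stood apart in the hCG share of listed reads (0.848) and in the share of the 10 most abundant genes (0.856). It is the embryo with 2 cells and an hCG share of 10.7%. In day 10 CTB the lowest embryo stood apart in implied depth (0.909). These are 3 of 38 sets tested, where chance at 1 in 20 gives 1.9, so single cases need no cause.

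The difference between STB and CTB was tested for a change from day 10 to day 12, and camera passed for 11 of 24 lists at the preset correlation. None passed with an estimated correlation, where the smallest adjusted p was 0.293. The medians of the 11 were 0.19 for placental hormones, 0.62 for pregnancy-specific glycoproteins, -1.498 for extravillous trophoblast, -0.99 for matrix proteases and basement membrane, -0.91 for interferon-stimulated genes, -1.12 for interferon ligands and receptors, -1.36 for S phase, -0.97 for G2 and M phase, 0.17 for oxidative phosphorylation, 0.89 for mitochondrially encoded genes and 0.18 for early response and heat shock. Without single sums they lay between -0.46 and 0.83 for hormones and -2.06 and 3.33 for glycoproteins (without day 12 STB of embryos 4 and 6), -0.24 and 2.12 for mitochondrially encoded genes (of 6 and 4), -0.03 and 0.44 for early response (day 12 STB and CTB of embryo 6), -0.06 and 0.61 for oxidative phosphorylation (day 10 STB of embryo 4 and day 12 CTB of embryo 3), and -1.59 and -0.61 for G2 and M phase (day 12 CTB of embryo 6 and STB of embryo 4). That of interferon-stimulated genes was -0.30 without day 12 CTB of embryo 3, and that of ligands and receptors -1.94 without day 12 STB of embryo 4. The calls of S phase and oxidative phosphorylation held without each sum in turn. Without day 12 CTB of embryo 3 camera passed 3 lists, without day 12 STB of embryo 4 it passed 6, and without that of embryo 6 the mitochondrially encoded, early response and ligand and receptor calls were lost (adjusted p = 0.578, 0.0733 and 0.326). With the embryo as a block medians were -0.09 for hormones, -0.79 for glycoproteins, -0.27 for interferon-stimulated genes and -0.06 for early response. No single gene passed in limma or voom, with 581 genes at an unadjusted p under 0.05 in limma.

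More genes were lower than higher in STB than in CTB over days 10 and 12, 95.9% of the calls. A few transcripts that take a large share of the reads lower all others on a CPM scale, and hCG genes took 39.5% of listed reads in day 10 STB against 22.7% in CTB. With median-of-ratios scaling 41.4% of calls were lower, but that scaling centres the genes, with an all-gene median of -0.02, so this value says nothing on the cause. Scaled without hCG and mitochondrial genes 68.5% were lower (all-gene median -0.13), short of an even split. Composition and a lowering of most genes in the syncytium cannot be told apart, since the table holds no measure of total RNA per cell.

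Mitochondrially encoded genes had a median log2 fold change of 1.87 in STB over CTB. The cells of day 12 embryo 6, rich in mitochondrial RNA, are excluded as the whole cause by a median of 1.25 without their sum, though 2 genes in place of 10 then passed. Median-of-ratios scaling (median 2.503) centres the genes, so scaling stays open, as does loss of cytoplasmic RNA from damaged cells in other embryos. A higher mitochondrial content of the syncytium is a hypothesis.

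HLA-G and KRT7 were higher in day 12 CTB of embryo 3 than of embryos 4 and 6. As a share of MTB RNA among these cells, HLA-G would need 0.682 on the profile of the numbered MTB cells and 0.198 on that of the unnumbered, and KRT7 0.431 and 0.380, beside a median of 0.112 over 16 MTB-rich genes and 0.199 over the 8 of them also rich in the unnumbered cells, so MTB cells or their RNA stay open. Depth and genes detected lay at most 7.96% outside the range of the other embryos, which excludes them. The mitochondrial share, 3.17% against 0.556 and 0.761%, lay 317% outside that range, so other library quality stays open. A difference between embryos, in timing for example, was not tested and cannot be told apart from library quality or MTB RNA.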

How the results depend on the processing

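The settings from RPKM values, median-of-ratios scaling, scaling without hCG and mitochondrial genes, voom, random embryo effects, list tests without single sums and the omission of shallow, mitochondria-rich or near-identical cells were chosen after seeing the data, and the others before the data were examined.

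The counts of called genes were 2246 for STB against CTB over both days (here STB-CTB), 1 at day 10, 1124 at day 12, 0 for the difference between days, 87 for MTB-CTB, 328 for MTB-STB, 1793, 2 and 709 for CTB day 10 against 8, 12 against 10 and 12 against 8, and 0 for STB between days. Values over 1.5 times apart follow.

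Quantile normalization of the log2 means gave 942 for STB-CTB, 0 at day 12 (2788 genes at an unadjusted p under 0.05), 156 for MTB-STB, 919 for CTB day 10 against 8 and 1 for 12 against 10. Median-of-ratios scaling gave 1037 for STB-CTB, 147 at day 12, 134 for MTB-CTB, 211 for MTB-STB and 808 for CTB day 10 against 8. Scaling without hCG and mitochondrial genes gave 861 for STB-CTB, 0 at day 10, 138 at day 12, 106 for MTB-STB, 891 for CTB day 10 against 8 and 1 for 12 against 10. The genes shared with the planned calls of STB-CTB were 485, 520 and 680 under these settings.

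RPKM as deposited gave 1294 for STB-CTB, 0 at day 10, 459 at day 12, 24 for MTB-CTB, 143 for MTB-STB, and 1167, 16 and 454 for CTB day 10 against 8, 12 against 10 and 12 against 8. Voom on estimated reads gave 0 at day 10, 168 at day 12, 32 for MTB-CTB, 98 for MTB-STB and 1 for CTB day 12 against 10. Limma without trend gave 0 at day 10. No filter on low values gave 0 at day 10, 519 at day 12, 569 for MTB-CTB, 793 for MTB-STB, 794, 6 and 342 for CTB day 10 against 8, 12 against 10 and 12 against 8, and 5 for STB between days. A pseudocount of 0.1 gave 0 at day 10, 88 for MTB-STB and 1 for CTB day 12 against 10. The mean over cells of log2 values gave 1327 for STB-CTB, 3 at day 10, 151 for MTB-STB and 83 for CTB day 12 against 10. Only the groups of the comparison gave 0 at days 10 and 12 (1891 and 2830 genes at an unadjusted p under 0.05), and 1128, 0 and 277 for CTB day 10 against 8, 12 against 10 and 12 against 8. Leaving out cells under 3 M reads, or the second cell of each close pair, gave 0 at day 10. Where a setting other than an omitted embryo gave 0 at day 10, 892 to 2062 genes had an unadjusted p under 0.05. The unnumbered MTB cells, of unknown embryo, as a second replicate gave 323 for MTB-CTB (145 higher) and 1309 for MTB-STB (1239 higher).

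With the embryo as a replicate block the counts were 0 at day 10 and 145 for MTB-CTB (117 higher, 57 shared with the 87), and 1724, 876 and 408 for STB-CTB, day 12 and MTB-STB. Camera with this block passed 3 lists at day 12 and 6 for the difference between days. Beyond the calls named with the block in the report, it ended those of CDKN2A, FGFR1, GRB10, HLA-G, MKI67, NDUFS1, PLK1, PMVK, SLC16A1, SRD5A1 and TPX2 in STB-CTB, of CCNB1, FGFR1, FN1, GADD45A, GATA3, MEST, NDUFS1, NDUFV1, PARP1, PGK1, SDHA, SLC16A1, STAT2, TAGLN2 and TPX2 at day 12, of CCNA2 and CCNB2 in MTB-CTB, and of CYSTM1, PGK1 and PKM in MTB-STB. It also ended the list calls of endoplasmic reticulum stress and secretion at day 12, and of hormones, pregnancy-specific glycoproteins, G2 and M phase and early response for the difference. It gave further list calls for pregnancy-specific glycoproteins at day 10 and in MTB-STB, endoplasmic reticulum stress and imprinted genes in both MTB comparisons, and early response in MTB-STB. It changed no other call of a named gene or list. As a random effect the embryo gave 1897 at day 12, 137 for MTB-CTB and 550 for MTB-STB.

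With an estimated correlation, the lists past the threshold went from 8 to 0 for STB-CTB, 10 to 0 at day 10, 8 to 0 at day 12, 11 to 0 for the difference, 11 to 5 for MTB-CTB, 12 to 3 for MTB-STB, 15 to 0, 7 to 0 and 16 to 3 for CTB day 10 against 8, 12 against 10 and 12 against 8, and 8 to 0 for STB between days.

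Without 1 embryo sum at a time, counts ranged from 594 to 2764 for STB-CTB, 0 to 2 at day 10, 0 to 1722 at day 12, 0 to 2 for the difference, 44 to 109 for MTB-CTB, 34 to 947 for MTB-STB, 458 to 3011, 0 to 45 and 243 to 1227 for CTB day 10 against 8, 12 against 10 and 12 against 8, and 0 to 4 for STB between days. Without day 12 CTB of embryo 3, camera passed 3 lists at day 12 and 3 for the difference, without day 12 STB of embryo 4 it passed 3 for STB-CTB, 3 at day 12, 6 for the difference and 2 for STB between days, and without day 10 CTB of embryo 3 it passed 11 for CTB day 12 against 10. The lowest of STB-CTB, day 12 and MTB-STB came without day 12 STB of embryo 6, and the highest of the difference, 2, without day 12 STB of embryo 4.

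Of 9718 values of named genes under alternatives, 8256 stayed as planned, 1419 lost their call, 43 gained one and 0 reversed. The planned tests for count data were not run.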

Other observations

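The pair-parting splits of the samples below were chosen after the results were seen, and the other splits before.

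Further single genes changed in CTB. WNT6, a WNT ligand gene, fell from 33.0 ± 16.6 CPM at day 8 to 3.84 ± 5.31 at day 10 (limma log2 fold change -3.22 ± 0.64, adjusted p = 0.00667), and FGFR1, a fibroblast growth factor receptor gene, changed by -2.54 ± 0.49, adjusted p = 0.00573. TFPI2, a serine protease inhibitor gene of the placenta, went from 0.401 ± 0.226 to 70.6 ± 110.4 (4.29 ± 0.80, adjusted p = 0.00504). SERPINE1, which inhibits plasminogen activators, rose (3.91 ± 0.82, adjusted p = 0.00846), while the cytoskeletal linker gene UTRN went from 39.5 ± 36.1 to 2.27 ± 1.91 (-3.45 ± 0.50, adjusted p = 0.00122). From day 8 to day 12 the growth factor gene IGF2 changed by 3.13 ± 0.58, adjusted p = 0.00495, the laminin gene LAMA1 by -3.87 ± 0.67, adjusted p = 0.00310 and the zinc transporter gene SLC39A8 by 4.37 ± 0.79, adjusted p = 0.00433. These genes passed without each embryo sum in turn.

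In STB against CTB over both days, the metalloproteinase gene ADAM8 (-2.52 ± 0.46, adjusted p = 0.00290), the imprinted zinc finger gene ZFAT (-1.93 ± 0.32, adjusted p = 0.00190) and the sterol sensor partner INSIG1 (-1.59 ± 0.33, adjusted p = 0.00510) were lower, and TMEM258, a subunit of the oligosaccharyltransferase, was higher (1.39 ± 0.31, adjusted p = 0.00769). Of the markers of other cell types, the endothelial cadherin gene CDH5 was 262 ± 144 in day 10 CTB and 737 ± 481 in day 12 CTB. PECAM1 was 32.0 ± 19.3 and the macrophage marker CD68 8.28 ± 3.80 in the latter. HLA-G reached 10 CPM in 7 of 26 CTB cells at day 8, 12 of 27 at day 10 and 31 of 32 at day 12.

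Other splits of the same sums tested each count against chance. For STB against CTB over both days, 1 of 100 splits drawn from 350 gave as many genes, the real one with 2246 against 1512 at most in the others, so chance is unlikely. For CTB day 10 against 8, 1 of 35 (the minimum) gave as many, 1793 against 729, and chance is unlikely there too. Chance is not excluded at day 10 (4 of 35, 1 gene against 37), for CTB day 12 against 10 (6 of 35, 2 against 6) and for CTB day 12 against 8 (3 of 35, 709 against 832). In the last, the highest other split set day 12 embryos 4 and 6 with day 8 embryo 4 against the rest. The split with 37 genes at day 10 set CTB of embryo 4 with STB. Of day 10 CTB that sum had the highest hCG share (35.3%), lowest CDH1 but highest KRT7. No cause was tested. Among splits that swap the lineages of whole pairs, 1 of 8 gave as many at day 10 (0 at most in the others), which is too few for a share under 1 in 20, and 1 of 32 over both days. The highest other there, 1512, swapped day 10 embryo 4 alone, and the next gave 1 gene.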
